A study of Mus musculus with 35 samples.

How the data were processed

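Hippocampal RNA from rTg4510 mice and from non-transgenic mice of the same mixed background was sequenced at 3, 6 and 9 months of age, giving 35 libraries. The rTg4510 line carries a mutant human tau transgene that is switched on in forebrain neurons, and it is used as a model of tauopathy. Ribosomal RNA was removed before sequencing, and the reads were paired, stranded and 76 bases long, per the labels. The source name of all 35 libraries gives the hippocampus, while their tissue entry gives a lysate of total brain, and the hippocampus named in the study description is used here.

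The deposited values are normalized counts, a signal obtained by dividing read counts by 1 factor per library, in a table of 1153 rows by 35 columns. Most rows are transposable element subfamilies with their family and class, such as B3 of the B2 family of SINEs. Some rows are other repeats, such as the satellite MMSAT4 or 7SK of the family RNA, and all rows are called elements here. The table used here holds no gene rows, and 20 of its rows are at 0 in every library. Trimmomatic, STAR, DESeq2 and the mouse build mm10 are named in the submitters' processing notes, without versions. The counting program, the repeat annotation and the treatment of reads that align to several places are not given in the sources used here. A row sums over all copies of a subfamily, so no single genomic position belongs to it, and copies inside introns or untranslated regions of genes may be part of the sum. Reads of closely related subfamilies can be shared between rows, which makes differences between near relatives uncertain.

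Every low value in a column was a whole multiple of 1 smallest step, so the reads behind each value could be recovered. All values (100%) came out within 0.01 of a whole number, and the largest distance was 3.52e-05. The deposited counts amount to 476049 to 1173360 reads per library, and the factors used by the authors ranged from 0.63 to 1.46. The median tested element had a mean of 109.7 recovered reads per library. Pairs of libraries, taken over all 35, differed by 1.67 to 301 times the chi-square expected from read sampling, so no library appeared to be deposited more than once.

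Groups were taken from the sample titles, which give genotype, age and a number read here as the number of the animal. The genotype in the characteristics disagrees with the title for 20 of the 35 libraries, namely 6 of 12 at 3 months, 6 of 12 at 6 months and 8 of 11 at 9 months. At 3 and 6 months both labels are exactly crossed, with 3 libraries in each combination. The choice of the title, the comparisons, the tests and most of the alternatives were fixed before the data were examined.

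The main test was limma 3.58.1 with an intensity trend, run in R 4.3.3 on log2(normalized count + 1), in 1 fit of all 35 libraries in 6 groups. Elements with a value of at least 10 in at least 5 libraries were kept, which left 916 tested elements and set aside 237 that hold 0.0592% of the reads. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested elements and a threshold of 0.05. Fold changes are on the log2(value + 1) scale and understate the change of elements with low values. Because the plan assumed a gene table, the lists of genes, the check of Mapt, Prnp and Fgf14 between genotypes and the Xist covariate could not be run. The sex of the animals is not given in the labels, so it was not used as a covariate.

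In their place, after seeing the data, 21 families of at least 4 tested elements, the 4 main classes and 2 lists drawn from element names were tested. The first of these holds 67 elements of families expanded in the mouse or rodent lineage, and the second 331 elements of families shared with other mammals. They were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The log2 ratios of B3 to B3A and to the sum of the other SINEs were used as measures that do not depend on the scaling. The level of a typical element in each library was taken as the median over elements of the ratio to the average of all libraries. Single values per library were compared with exact permutation tests, two-sided, over all splits of the libraries of 1 age. A difference between ages in the genotype effect on such a value was tested by shuffling residuals within age 100000 times.

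Named elements follow a rule fixed beforehand. For each genotype comparison it takes, among elements past the threshold with a mean of at least 50, the 6 largest positive and the 6 largest negative fold changes, and up to 3 members with the smallest p in each list that passed or had 3 or more members past the threshold. For comparisons of ages and of differences it takes the 4 largest each way. The rule was applied both to the deposited scale and to values rescaled with TMM factors, because at 9 months rescaling moved the median of all elements from -0.39 to -0.02, a shift of more than 0.1. Using both scales was decided after the data were seen. B3A and other B2 members were named after their values were seen.

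Alternatives fixed beforehand were grouping by the characteristics, libraries whose labels give the same genotype, the characteristics or the lane as covariates, pseudocounts of 0.5 and 8, no filter or a filter of 50, 3 other scalings, limma with robust estimation or array weights, a fit of only the ages compared, leaving out each library, and count tests. The count tests were the quasi-likelihood test of edgeR 4.0.16 and the test of DESeq2 1.42.0 on the recovered reads with the deposited factors. At 9 months they called 431 and 444 elements. Alternatives without Sample_207 and Sample_208, within single lanes, with lanes 1 and 4 set against lanes 5 to 8, with the characteristics as 1 covariate over all ages or as groups within single lanes, and edgeR with TMM factors were added after seeing the data. Sample_207 and Sample_208 were singled out because their columns stand among those of the other genotype in the table, and their B3 ratios were looked at as well. For these comparisons p-values measure the spread between animals as numbered in the titles.

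The limma step was tested on simulated counts drawn from the real means, factors and dispersions, with 200 of the 916 elements changed. For the comparison at 3 months it recovered 45 of 67 elements changed 1.5-fold, 58 of 67 changed 2-fold and 66 of 66 changed 4-fold, and called 6 of 716 unchanged elements. For the comparison at 9 months it recovered 49 of 67, 63 of 67 and 66 of 66, and again called 6 of 716. The simulation drew each element on its own and held no shift shared by the elements of a library. Its rates therefore need not hold for the real libraries, where random regrouping at 3 months gave up to 165 elements past the threshold.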

Results

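Transposable element RNA was measured in the hippocampus of rTg4510 mice, which express mutant human tau in forebrain neurons, and of non-transgenic mice. The 35 libraries comprised 6 non-transgenic and 6 rTg4510 libraries at 3 months, 6 and 6 at 6 months, and 6 and 5 at 9 months. Reads assigned to elements ranged from 476049 to 1173360 per library, with a mean of 761411 ± 157416 (SD, n = 35). The comparisons asked which elements differed between genotypes at each age, whether that difference changed with age, and how levels changed with age within a genotype.

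SINEs, short elements copied through RNA, made up the largest share of the signal among the classes. Leaving aside ORR1A4 and L1Md_T, whose share of a library varied from 0.185% to 12.8% and from 0.201% to 14.2%, SINEs held 47.1% ± 0.54 (SD, n = 35) of the normalized counts. LTR elements, the remains of retroviruses and their relatives, held 24.8% ± 0.37, LINEs 19.8% ± 0.49 and DNA transposons 6.50% ± 0.21 over the same 35 libraries. B3, an old rodent SINE of the B2 family, averaged 29360 normalized counts, ID_B1 averaged 26721 and MIRb, a SINE shared by mammals, averaged 18312.

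The abundance of B3 relative to its close relative B3A separated the genotypes given in the titles. This ratio was chosen after its values were seen, and its exact p-values do not account for that choice. At 3 months the log2 ratio of B3 to B3A was 1.54 ± 0.027 (SD, n = 6) in rTg4510 and 1.26 ± 0.022 (SD, n = 6) in non-transgenic libraries, a 1.21-fold difference with an exact permutation p of 0.00216, the smallest that 924 splits allow. At 6 months it was 1.51 ± 0.053 against 1.26 ± 0.030 (n = 6 each, exact permutation p = 0.00216). At 9 months the ratio was 1.45 ± 0.069 (n = 5) against 1.27 ± 0.097 (n = 6), with an exact permutation p of 0.0130. Within lane 6 at 3 months the difference was 0.29 (exact permutation p = 0.00794) and within lane 7 at 6 months 0.26 (exact permutation p = 0.0286). At 9 months it was 0.14 within lane 1 (exact permutation p = 0.143) and 0.27 within lane 8, where the smallest possible p is 0.333. Relative to the sum of all other SINEs, B3 differed by 0.31 at 3 months and 0.25 at 6 months (log2, exact permutation p = 0.00216 each), but by 0.01 at 9 months (exact permutation p = 0.835), or 0.07 without Sample_207 and Sample_208. Grouped by the genotype in the characteristics, the ratio of B3 to B3A differed by -0.02, -0.01 and -0.08 at 3, 6 and 9 months, with exact permutation p of 0.643, 0.885 and 0.279.

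**Figure D1:**
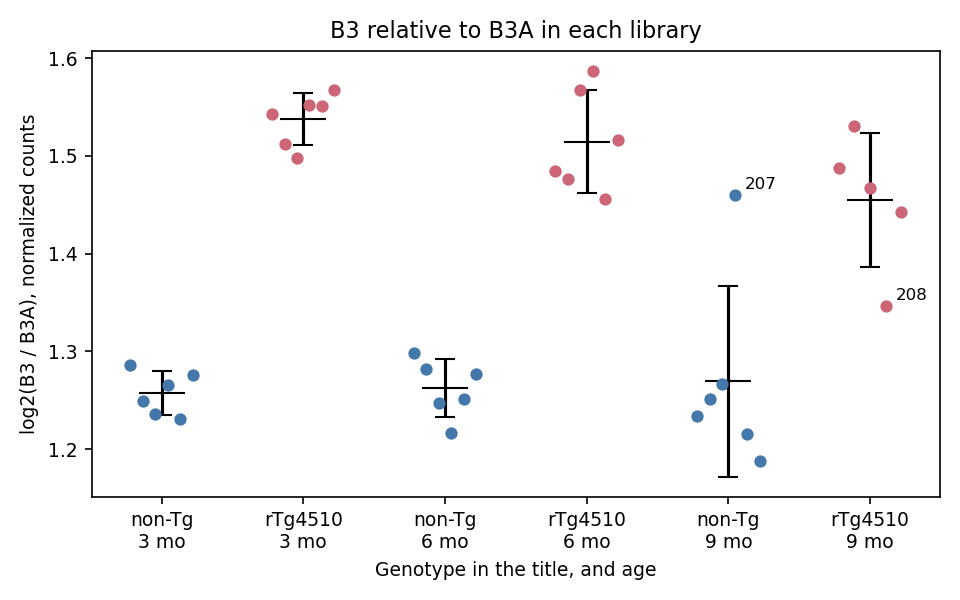
Each point is the log2 ratio of B3 to B3A normalized counts in 1 library, by genotype in the title and age, with the group mean and SD as bars. Apart from Sample_207 and Sample_208, rTg4510 libraries lay between 1.44 and 1.59 and non-transgenic libraries between 1.19 and 1.30.

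The libraries labelled Sample_207 and Sample_208 departed from this separation. Sample_207, titled non-transgenic, had a ratio of 1.46, inside the range of 1.44 to 1.59 of the other 16 rTg4510 libraries. Sample_208, titled rTg4510, had a ratio of 1.35, between that range and the range of 1.19 to 1.30 of the other 17 non-transgenic libraries. Without both, the difference at 9 months was 0.25 (n = 4 and 5), for which no p is given because the ratios of these libraries had been looked at. Both were kept under their titles, and some values without them are given beside the main values at 9 months. Leaving them out after their values had been looked at favours a difference by title, so adjusted p without them do not test chance.

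At 3 months B3 was the element that differed between genotypes, and this became visible once values were rescaled. After TMM rescaling B3 was 1.23-fold higher in rTg4510 (log2 fold change 0.29, SE 0.026, limma adjusted p = 1.77e-10), and on the deposited scale its log2 fold change was 0.38 with an adjusted p of 0.982. The other B2 members gave log2 fold changes of 0.01 for B3A, 0.05 for B2_Mm2, 0.02 for B2_Mm1t and -0.01 for B2_Mm1a on the rescaled values. As a list, the 5 B2 members passed camera on these values (adjusted p = 0.000164), with 1 of 5 members past the threshold and an adjusted p of 0.176 with an estimated correlation. On the deposited scale limma called 0 of 916 elements, as did edgeR and DESeq2, with 19 at an unadjusted p under 0.05. The median log2 fold change of all elements was 0.08.

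At 6 months B3 was again higher in rTg4510, 1.19-fold after TMM rescaling (log2 fold change 0.24, SE 0.026, adjusted p = 2.59e-08), while its log2 fold change on the deposited scale was 0.21 (adjusted p = 0.997). B3A gave -0.01 and B2_Mm2 -0.02 on the rescaled values. MamGypLTR3a, an ancient mammalian LTR of the Gypsy group, gave a log2 fold change of -0.82 on the deposited scale (adjusted p = 0.396). In the fit without Sample_207 and Sample_208, which belong to another age but share in the estimate of spread, the same change had an adjusted p of 0.0102. The L2 family passed camera after rescaling (4 members, median -0.09, adjusted p = 0.0264), with 0 members past the threshold and an adjusted p of 0.658 with an estimated correlation. On the deposited scale limma called 0 elements, as did edgeR and DESeq2, with 20 at an unadjusted p under 0.05.

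At 9 months most elements were lower in rTg4510 than in non-transgenic hippocampus on the deposited scale. The log2 fold change was negative for 859 of 916 elements (93.8%), with a median of -0.39, a fold of 0.764. Limma called 445 elements lower and 1 higher, MamRep1894, and without Sample_207 and Sample_208 it called 467 lower and 8 higher. The level of a typical element was -0.12 ± 0.20 (log2, SD, n = 5) in rTg4510 and 0.25 ± 0.19 (n = 6) in non-transgenic libraries, a difference of -0.37 with an exact permutation p of 0.0152 (adjusted over 3 ages, 0.0455). At 3 and 6 months the same difference was 0.08 (exact permutation p = 0.578) and -0.02 (exact permutation p = 0.812). Within lane 8 the 9-month difference was -0.56 (2 against 2, smallest possible p 0.333), and within lane 1 it was -0.25 (3 against 4, exact permutation p = 0.229), with 519 and 0 elements called lower. Leaving out Sample_203 (rTg4510) left 225 calls and leaving out Sample_213 (non-transgenic) 238, and adding the characteristics as a covariate within each age left 232. Grouped by the characteristics, limma called 0 elements, with 334 at an unadjusted p under 0.05 and a median of 0.28, and the typical level differed by 0.27 (exact permutation p = 0.102). The characteristics disagree with the title for 8 of 11 libraries at this age, so this grouping is largely the reverse of that by title.

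**Figure D2:**
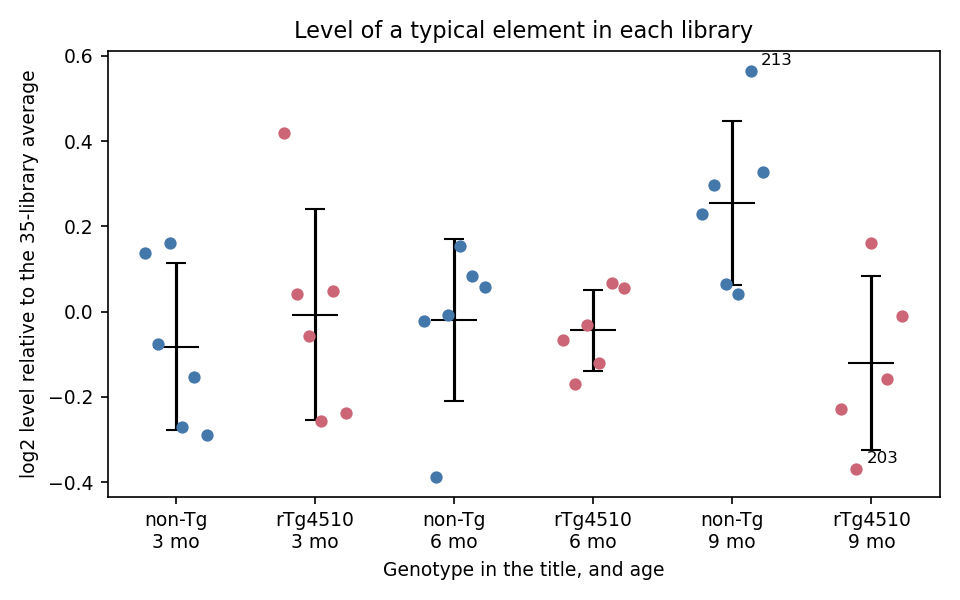
Each point is the log2 level of a typical element in 1 library relative to the average of the 35 libraries, by genotype in the title and age, with the group mean and SD as bars. At 9 months the non-transgenic mean was 0.25 and the rTg4510 mean -0.12, and Sample_203 and Sample_213 were the lowest and highest of that age.

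TMM rescaling, which removes the shared shift of -0.39, left 29 of the 445 lower elements past the threshold as lower and turned 0 of them to higher. Relative to that shift limma called 52 elements higher and 29 lower, and without Sample_207 and Sample_208 it called 95 higher and 83 lower. Of these, 50 higher and 27 lower elements were called in both fits. The 52 higher and 29 lower became 126 and 111 without Sample_207, 107 and 74 without Sample_205, 93 and 64 without Sample_206, 75 and 47 without Sample_180, 32 and 21 without Sample_214, 29 and 19 without Sample_204, 23 and 12 without Sample_203, and 16 and 11 without Sample_213. Within lane 8 alone 16 elements were called, all higher, and within lane 1 alone 0, with 46 at an unadjusted p under 0.05.

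L1ME3G, an ancient member of the L1 family of LINEs, had the smallest p on the deposited scale. It fell from 501 ± 187 (SD, n = 6) to 200.4 ± 56.8 (n = 5) normalized counts, a log2 fold change of -1.26 (SE 0.22, adjusted p = 0.000511), and by 0.88 on the log2 scale after rescaling (adjusted p = 0.00825), or 1.20 without Sample_207 and Sample_208 (adjusted p = 2.54e-07). The L1 family had 86 of 123 members lower on the deposited scale, 93 when adjusted over the list alone, with a median of -0.46 and no member higher. It passed camera as lower than the other elements (adjusted p = 0.00381), with an adjusted p of 0.988 with an estimated correlation. L1MA6 (-0.56, adjusted p = 0.00334) and L1_Mm (-0.66, adjusted p = 0.00334) were its next members on the deposited scale, at -0.18 and -0.28 after rescaling (adjusted p = 0.120 and 0.119), and L1_Mm was at -0.06 without Sample_207 and Sample_208 (adjusted p = 0.746). After rescaling 4 L1 members were higher and 3 lower. LINEs as a class gave 95 of 142 lower, a camera adjusted p of 0.0145 and 0.988 with an estimated correlation.

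Among the LTR elements of the ERVK group, which includes the youngest mouse retroviruses, 121 of 253 were lower on the deposited scale and 0 higher. Over all 916 tested elements 48.6% were lower, and the shares in ERVK, ERVL, ERV1, hAT-Charlie and TcMar-Tigger were no larger. IAPEY4_I-int, an internal part related to intracisternal A particles, fell by 1.02 on the log2 scale (SE 0.21, adjusted p = 0.0023) and by 0.64 after rescaling (adjusted p = 0.00825). The sex of the animals is not given, and a difference in sex between the groups was not tested for this change. Repeats of the Y chromosome, such as CYRA11_Mm, were among the tested elements but were not used to infer sex. RLTR11C_MM (-0.85) and RLTR10-int (-0.78) were also lower, and remained so after rescaling at -0.48 and -0.41 (adjusted p = 0.00825 for both). In the opposite direction RLTR44-int (0.59, adjusted p = 0.00825) and RLTR44C (0.55, adjusted p = 0.0131) of the same group were higher after rescaling, at 0.21 and 0.17 on the deposited scale (adjusted p = 0.185 and 0.269). After rescaling 12 ERVK members were higher and 8 lower, or 11 and 7 when adjusted over the list alone. The camera adjusted p of the group was 0.446 on those values.

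The ERVL-MaLR group, old non-autonomous LTR elements, had 60 of 92 members lower on the deposited scale, and ERVL 44 of 91. ORR1C1-int (-0.84) and MTC-int (-0.68) of the first group and MER77B (-0.86) of the second were lower, and after rescaling stood at -0.46, -0.30 and -0.49 (adjusted p = 0.00868, 0.00921 and 0.0131). MLT1H-int was higher after rescaling (0.56, adjusted p = 0.0217). In ERV1 43 of 100 members were lower, among them LTRIS4 (-0.96, adjusted p = 0.0068) and MuLV-int, the internal part of murine leukemia viruses (-1.44, adjusted p = 0.00344, mean 9.25 normalized counts). After rescaling LTRIS4 was at -0.59 (adjusted p = 0.0830), or -0.86 without Sample_207 and Sample_208 (adjusted p = 0.00770), MuLV-int at -1.11 (adjusted p = 0.0184) and RLTR30D_MM was higher (0.53, adjusted p = 0.0223).

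Ancient LTR elements of the Gypsy group went in both directions. LTR81B fell by 1.27 on the log2 scale (SE 0.27, adjusted p = 0.00249) and by 0.90 after rescaling (adjusted p = 0.0186). MamGypLTR3a fell by 0.96 (adjusted p = 0.00429), and after rescaling it was at -0.59 (adjusted p = 0.0888), or -1.13 without Sample_207 and Sample_208 (adjusted p = 1.34e-06). LTR104_Mam was 1.61-fold higher after rescaling (0.69, SE 0.17, adjusted p = 0.0116), 0.98 without both animals (adjusted p = 1.75e-07), and 0.31 on the deposited scale (adjusted p = 0.0906). The 13 members passed camera on the deposited scale as less lowered than other elements (adjusted p = 0.0471), with 0.988 with an estimated correlation.

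Fossil DNA transposons were likewise divided. Of 63 hAT-Charlie members 21 were lower on the deposited scale, and after rescaling 4 were higher and 4 lower. Charlie8 was 1.55-fold higher after rescaling (0.63, SE 0.14, adjusted p = 0.00825, deposited scale 0.25 with adjusted p = 0.114), and Charlie4a was lower on both scales (-0.84 and -0.47, adjusted p = 0.00334 and 0.0204). Tigger10 was lower on the deposited scale (-0.94, adjusted p = 0.00334) and at -0.57 after rescaling (adjusted p = 0.0577), or -0.70 without Sample_207 and Sample_208 (adjusted p = 0.0170). Of 37 TcMar-Tigger members 15 were lower on the deposited scale.

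SINEs were lower on the deposited scale for 20 of 35 members, with 4 higher and 3 lower after rescaling. B2_Mm2 (-0.50, adjusted p = 0.00502), B3A (-0.49, adjusted p = 0.00536) and RSINE1 of the B4 family (-0.52, adjusted p = 0.00512) were lower on the deposited scale, and at -0.12, -0.11 and -0.14 after rescaling (adjusted p = 0.0440, 0.0223 and 0.0203). B3 was at -0.30 (adjusted p = 0.0539) on the deposited scale and 0.07 (adjusted p = 0.0631) after rescaling, or 0.11 without Sample_207 and Sample_208. The 16 Alu-related members all lay above 0 after rescaling, with a median of 0.09, 1 past the threshold and 5 when adjusted over the list alone. They passed camera there (adjusted p = 0.00335), with 0.661 with an estimated correlation, and on the deposited scale their median was -0.29. Without Sample_207 and Sample_208, 3 of the 16 lay below 0 after rescaling, and the camera adjusted p was 0.208.

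**Figure D3:**
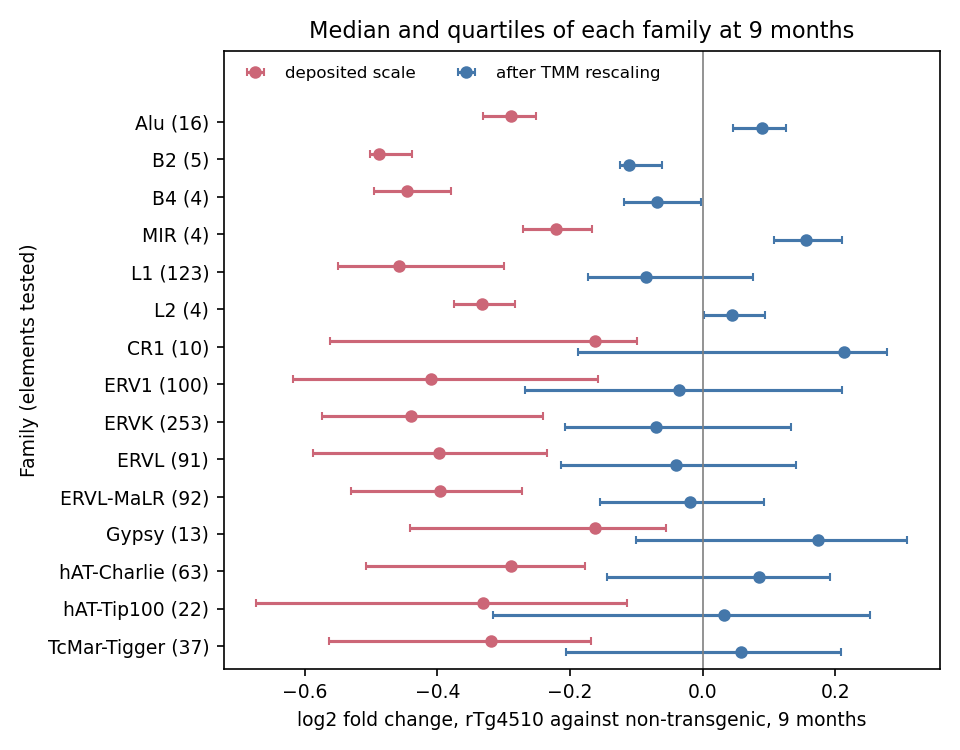
Points are the median log2 fold change of the tested elements of each family at 9 months, rTg4510 against non-transgenic, and bars run between the quartiles. Among the families drawn, the medians on the deposited scale were all below 0, with L1 at -0.46 and MIR at -0.22, and after TMM rescaling they ran from -0.11 for B2 to 0.21 for CR1.

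Of the 2 lists drawn from element names, both lay below 0 on the deposited scale. The 67 elements of families expanded in mouse or rodents had a median of -0.45 with 31 lower and 0 higher, and the 331 elements shared with other mammals a median of -0.32 with 122 lower and 0 higher. The second list passed camera as less lowered than other elements (adjusted p = 0.0443), with 0.988 with an estimated correlation, and 0.0638 after rescaling.

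The genotype difference at 9 months was itself different from that at 3 months. The difference of differences had a median of -0.48, with 300 of 916 elements past the threshold, all lower, and 9 higher and 13 lower after TMM rescaling. L1ME3G (-1.53, adjusted p = 0.00387), LTR81B (-1.36, adjusted p = 0.0180), IAPEY4_I-int (-1.19, adjusted p = 0.0122) and MER77B (-1.18, adjusted p = 0.00387) showed the largest differences. Relative to the shift, L1ME3G stood at -1.06, MER77B at -0.73, RLTR19A at 0.64 and MER34A at 0.61 (adjusted p = 0.0197, 0.0187, 0.0177 and 0.0187). For the level of a typical element the difference was -0.45 (permutation p = 0.0160, adjusted 0.0336). The 300 elements are 32.8% of those tested, and this share was 21.4% without Sample_170, 21.1% without Sample_208, 20.3% without Sample_199, 18.4% without Sample_214, 16.3% without Sample_176, 6.77% without Sample_166, 3.60% without Sample_203, 3.49% without Sample_180, 2.29% without Sample_213 and 0.655% with lane as a factor.

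Against 6 months, the genotype difference at 9 months differed for 1 element, IAPEY4_I-int (-1.29, adjusted p = 0.0342), with 292 at an unadjusted p under 0.05. This count was 0 with lane as a factor or without any 1 of 11 libraries, and it rose to 12.8% of elements without Sample_207, 20.3% without Sample_205 and 25.3% with array weights. After rescaling the difference was past the threshold for IAPEY4_I-int (-0.95) and B3 (-0.17), with an adjusted p of 0.0283 for both, and for 12 higher and 3 lower elements without Sample_207 and Sample_208. The typical level differed by -0.35 (permutation p = 0.0224, adjusted 0.0336). Between 6 and 3 months 0 elements differed by limma, edgeR or DESeq2, with 14 at an unadjusted p under 0.05. For the ratio of B3 to B3A the genotype difference did not differ detectably between 9 and 3 months (-0.09, permutation p = 0.0686), and it was -0.03 without Sample_207 and Sample_208.

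Within non-transgenic mice, elements were higher at 9 than at 6 months on the deposited scale by a median of 0.28, a fold of 1.21. After TMM rescaling the median was 0.02, with 6 elements higher and 10 lower, or 1 and 3 without Sample_207 and Sample_208. On the deposited scale RLTR53_Mm (0.78, adjusted p = 0.0377), RMER20C_Mm (0.66, adjusted p = 0.0377) and RLTR45 (0.66, adjusted p = 0.0458) were past the threshold. ORR1A4, a mouse MaLR element, fell by 3.45 (adjusted p = 0.0377). These 4 calls were 0 with lane as a factor, 60 by edgeR, 146 by DESeq2, 149 higher and 2 lower without Sample_207 and Sample_208, and from 0% to 20.3% of elements when single libraries were left out. Of the 9-month non-transgenic libraries 4 of 6 came from lane 1, which held no library of 6 months. Within rTg4510 mice 0 elements passed between 9 and 6 months on the deposited scale by limma, edgeR or DESeq2, with 109 at an unadjusted p under 0.05. After rescaling 35 were higher and 22 lower, led by L1MEg2 (0.67), UCON6 (0.63), L1ME3G (-0.75) and Tigger10 (-0.70), and with lanes 1 and 4 set against lanes 5 to 8 these were 0. Between 6 and 3 months limma called 0 elements in either genotype, as did edgeR and DESeq2.

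ORR1A4 followed the sequencing lane, and L1Md_T, a young LINE, did so in part. In lanes 1 and 4 ORR1A4 had 1377 to 2319 normalized counts at 9 months (n = 7) and 1731 to 1789 at 3 months (n = 2), and in lanes 5 to 8 it had 12317 to 87129 at 9 months (n = 4) and 23395 to 74980 at 3 months (n = 10). The difference was 23.2-fold at 9 months (exact permutation p = 0.00303) and 26.3-fold at 3 months (exact permutation p = 0.0152). L1Md_T differed 11.3-fold and 12.5-fold between the same lanes at these ages, with the same exact permutation p. At 6 months, where all libraries came from lanes 5 to 8, L1Md_T ran from 1549 to 126464, which overlaps the 1455 to 2758 of lanes 1 and 4 at 9 months. The lane difference was not limited to these elements. With the groups in the fit and after rescaling, 42 of 916 elements were higher and 62 lower in lanes 1 and 4 than in lanes 5 to 8, among the latter ETnERV2-int (-1.38, adjusted p = 0.000653) and L1MEd (-1.10, adjusted p = 2.81e-05).

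**Figure D4:**
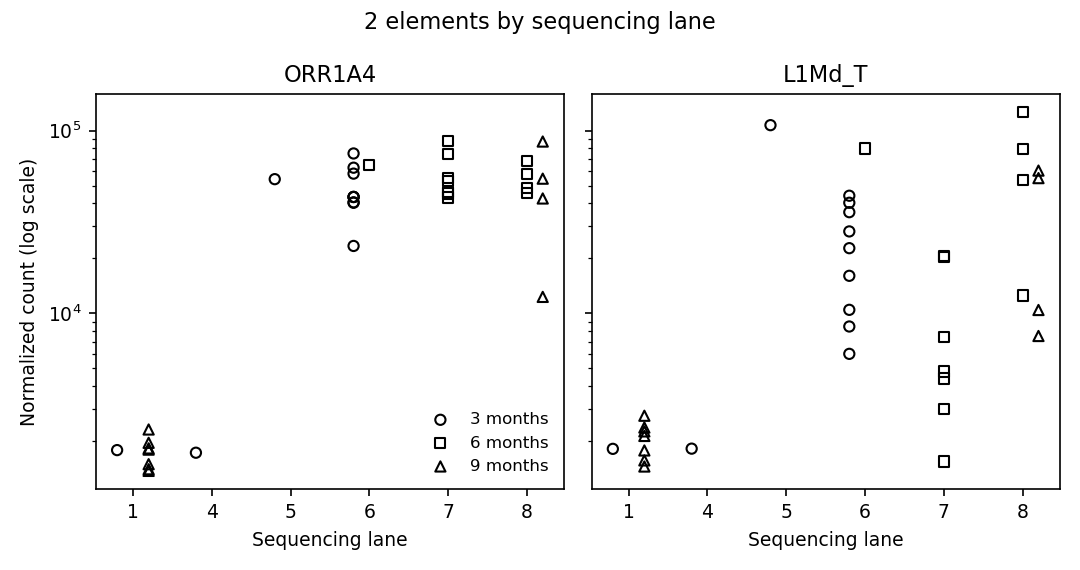
Each point is the normalized count of ORR1A4 or L1Md_T in 1 library on a log axis, by sequencing lane, with a marker for each age. Libraries of lanes 1 and 4 lay between 1377 and 2319 for ORR1A4, and those of lanes 5 to 8 at 12317 or more, while for L1Md_T the libraries of lanes 5 to 8 reached down to 1549.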

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

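The tests of the explanations, the splits of libraries and the tests of the typical level in this part were chosen only after the results had been seen, while the comparisons between ages on the deposited scale were planned, with TMM rescaling as an alternative.

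Lower levels of most elements in rTg4510 at 9 months came with 445 elements past the threshold as lower. The tables argue against the lane, since 483 elements were lower with lane as a factor. The shift did not rest on Sample_207 and Sample_208 alone, since 467 elements were lower without them. Sample_207 had the lowest typical level of the non-transgenic libraries of that age (0.04), so leaving it out favours the shift. A fit with the labels of Sample_207 and Sample_208 exchanged was not run, so the effect of wrong labels on its size is not known. The lane factor does not tell whether both lanes hold the shift. The typical level differed by -0.25 within lane 1 (3 against 4, exact permutation p = 0.229) and by -0.56 within lane 8 (2 against 2). With the genotype in the characteristics as 1 covariate over all ages, 244 elements were still called lower. This argues against a trait that follows that label as the whole cause. The fall from 445 to 244 leaves open that such a trait is a part of it. A factor per library shared by all elements cannot be told from a real loss of element RNA, because TMM rescaling, after which 29 of the 445 elements were still called lower, removes either. The authors' normalization on genes that this table does not hold stays open, where the deposited factors followed those from the elements alone at r = 0.75 and the typical level followed the log factor at r = -0.50, neither of which tests it, and an effect of the transgene on element RNA as a whole is an untested biological explanation.

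B3 was higher in rTg4510 relative to its relative B3A, at 9 months more through a lower B3A (-0.11 after TMM rescaling) than through a higher B3 (0.07). The lane is argued against by the difference of 0.29 in the log2 ratio within lane 6 at 3 months, against 0.28 over all lanes, and a rise of the whole B2 family by the median log2 fold change of 0.02 (0.0186) of the other members at 3 months after TMM rescaling, against 0.29 for B3. A wrong genotype label on Sample_207 is a candidate explanation of its place, since on the elements called without it and Sample_208 it scored 1.12, on a scale with the mean of the other non-transgenic libraries at 0 and of the other rTg4510 libraries at 1, where the other rTg4510 libraries ran from 0.74 to 1.33 and the other non-transgenic libraries from -0.15 to 0.15. These elements were chosen because they separate the other libraries, so the gap between the ranges is widened by that choice. Only Sample_207 and Sample_208 took no part in it. A swap of Sample_207 and Sample_208 cannot be told apart from a single wrong label, since Sample_208 scored 0.723, near the rTg4510 libraries, while its MamGypLTR3a level of 7.79 lay above the 6.67 to 7.24 of the other non-transgenic libraries and its RLTR45-int level of 5.56 below their 5.77 to 6.30, although Charlie8 (10.3) and RLTR44-int (8.54) lay inside the rTg4510 ranges and L1ME3G (8.03) and LTR104_Mam (10.9) nearer to them. The columns of Sample_207 and Sample_208 each stand among those of the other genotype, which goes with a swap. The characteristics also give each the genotype opposite to its title. That label disagrees with the title for 8 of 11 libraries at 9 months, so it does not decide the question. Reads of single B3 copies inside genes, including genes that differ between the strains or near the transgene, stay open and could not be tested without positions.

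ORR1A4 split by lane, and L1Md_T did so with an overlap at 6 months. The fold of 23.2 for ORR1A4 within 9 months between lanes 5 to 8 and lanes 1 and 4 is the pattern itself, so it does not test a batch that follows the lane, which stays open. Age is argued against for ORR1A4 by the fold of 0.707 between 9 and 6 months within lanes 5 to 8. What the batch was is not given in the labels, and no biological explanation was tested beyond age.

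Splits of the same libraries into groups of the same sizes, 100 for each count and the real one included, were set against the counts. For the genotype at 9 months 3 of 100 splits gave as many elements as the real 446 (highest other 554). For its difference from 3 months 3 gave as many as 300 (highest other 428), and for its difference from 6 months 2 gave as many as 1 (highest other 8). Each share is below 0.05, but without adjustment for the number of counts examined, so chance is not excluded for these counts. These splits ignore the lane, and with lane as a factor the shares for the differences from 3 and 6 months fell to 0.655% and 0%, against 37.0% and 0.328% with lanes 1 and 4 set against lanes 5 to 8. The count of 1 also fell to 0 without any 1 of 11 libraries. For age 9 against 6 months in non-transgenic mice 3 splits were as large as the real 4 (highest other 8), but with lane as a factor the count was 0. For the counts of 0, all 100 splits gave as many: genotype at 3 months (highest other 165), genotype at 6 months (0), the difference between them (0), age 6 against 3 months in non-transgenic mice (0) and in rTg4510 mice (0), and age 9 against 6 months in rTg4510 mice (3). The split with 165 elements at 3 months, where the real one gave 0, points to a structure of the samples other than the genotype in the title, which was not tested further. The splits with 554 and 428 also gave more elements than the real ones.

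After TMM rescaling chance cannot be excluded for the 81 elements at 9 months, where 7 of 100 splits gave as many and the highest other gave 277, which again points to a structure of the samples. Without Sample_207 and Sample_208 only the real split (1 of 100) gave as many, with 19.4% of elements past the threshold against 19.1% in the highest other, but these libraries were left out after their values had been looked at, which favours the real split, so this does not test chance. For the single element at 3 months 6 splits gave as many, and for that at 6 months 5, with a highest other of 1 in both, so the count of 1 does not exclude chance. That count does not tell which element was called, and B3 had adjusted p of 1.77e-10 and 2.59e-08 over the 916 elements. For the difference between 9 and 3 months 3 splits gave as many as 22 (highest other 53), and for age 9 against 6 months in rTg4510 mice 1 gave as many as 57 (highest other 4). These splits ignore the lane, and with lanes 1 and 4 set against lanes 5 to 8 the count of 57 fell to 0.

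A library stood apart from the others of its group in 14 of 72 groups of values tested, where chance gives about 1 in 20. The groups are not independent, and 8 of the 14 values belong to Sample_207, so this share is not a test. The log2 level of ORR1A4 was 10.8 in non-transgenic Sample_167 at 3 months (others 15.3 to 15.9) and 10.8 in rTg4510 Sample_166 at 3 months (others 14.5 to 16.2). These were the only libraries of lanes 1 and 4 at that age, so both values repeat the lane split of ORR1A4. On the log2 scale ORR1A4 was at 16.4 in rTg4510 Sample_186 at 6 months (others 15.5 to 15.8). The typical level was -0.39 in non-transgenic Sample_183 at 6 months (others -0.02 to 0.15). In non-transgenic Sample_207 the log2 ratio of B3 to B3A was 1.46 (others 1.19 to 1.27). On the log2 TMM scale the same animal had LTR81B at 4.51, L1ME3G at 7.40, LTRIS4 at 4.66, LTR104_Mam at 11.6, Charlie8 at 10.8, RLTR44-int at 8.96 and RLTR44C at 8.56. In rTg4510 Sample_208 MamGypLTR3a was at 7.79, and in rTg4510 Sample_203 MLT1H-int was at 8.96 (others 8.57 to 8.68).

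The genotype difference at 9 months differed from that at 6 months for 1 element on the deposited scale and 2 after TMM rescaling, by the interaction term. From that at 3 months it differed for 300 elements and 22 after TMM rescaling, or 58 higher and 40 lower after TMM rescaling without Sample_207 and Sample_208. The share of 32.8% behind the 300 fell to 0.655% with lane as a factor and to as little as 2.29% when 1 library was left out. The genotype difference in the typical level changed by -0.45 between 3 and 9 months and by -0.35 between 6 and 9 months, by permutation.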

How the results depend on the processing

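The alternatives fixed beforehand were run for every comparison, except the covariate for Xist and the alternatives for gene lists, which were not run because the table holds no genes. Those without Sample_207 and Sample_208, within or between lanes, with the characteristics as 1 covariate, with edgeR on TMM factors, and all tests of the typical level, of the B3 ratio and of families were chosen after seeing the data. Shares below are elements past the threshold among those tested, given where their number moved by more than 1.5 times, against 0, 0 and 48.7% for genotype at 3, 6 and 9 months. For genotype by age they stand against 0 (6 against 3 months), 0.109% (9 against 6) and 32.8% (9 against 3). For age 6 against 3 and 9 against 6 months they stand against 0 and 0.437% in non-transgenic and 0 and 0 in rTg4510 mice.

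Grouped by the genotype in the characteristics, the shares were 0% for genotype at 9 months, 0% for genotype by age 9 against 6, 0% for genotype by age 9 against 3, 0% for age 9 against 6 in non-transgenic and 0.109% for age 9 against 6 in rTg4510. In libraries whose labels give the same genotype, the shares were 0.218% for genotype at 3 months, 0.437% for genotype at 6 months, 1.09% for genotype at 9 months, 0.218% for genotype by age 6 against 3, 0.437% for genotype by age 9 against 6, 1.86% for genotype by age 9 against 3, 0.109% for age 6 against 3 in non-transgenic, 0.437% for age 6 against 3 in rTg4510 and 0.764% for age 9 against 6 in rTg4510. At 9 months that leaves 1 rTg4510 and 2 non-transgenic libraries, so these values assume that the single rTg4510 library varies like those of the other groups. With the characteristics as a covariate within each age, the shares were 25.3% for genotype at 9 months, 0% for genotype by age 9 against 6, 6.88% for genotype by age 9 against 3 and 0% for age 9 against 6 in non-transgenic. With lane as a factor, the shares were 0% for genotype by age 9 against 6, 0.655% for genotype by age 9 against 3 and 0% for age 9 against 6 in non-transgenic. Pseudocount 8 gave 0.764% for age 9 against 6 in non-transgenic. Without a filter, the shares were 0% for genotype by age 9 against 6 and 0% for age 9 against 6 in non-transgenic. A filter of 50 gave 5.61% for age 9 against 6 in non-transgenic. TMM rescaling gave 0.109% for genotype at 3 months, 0.109% for genotype at 6 months, 8.84% for genotype at 9 months, 0.218% for genotype by age 9 against 6, 2.40% for genotype by age 9 against 3, 1.75% for age 9 against 6 in non-transgenic and 6.22% for age 9 against 6 in rTg4510. Median-of-ratios rescaling gave 0.109% for genotype at 3 months, 0.109% for genotype at 6 months, 9.93% for genotype at 9 months, 0.218% for genotype by age 9 against 6, 2.40% for genotype by age 9 against 3, 1.42% for age 9 against 6 in non-transgenic and 4.48% for age 9 against 6 in rTg4510. Quantile normalization gave 7.53% for genotype at 9 months, 0% for genotype by age 9 against 6, 1.20% for genotype by age 9 against 3, 1.64% for age 9 against 6 in non-transgenic and 3.49% for age 9 against 6 in rTg4510. Robust estimation gave 0.328% for genotype by age 9 against 6 and 8.41% for age 9 against 6 in non-transgenic. Array weights gave 0.764% for genotype at 6 months, 0.109% for genotype by age 6 against 3, 25.3% for genotype by age 9 against 6, 51.2% for genotype by age 9 against 3, 0.764% for age 6 against 3 in non-transgenic, 41.6% for age 9 against 6 in non-transgenic, 0.873% for age 6 against 3 in rTg4510 and 0.218% for age 9 against 6 in rTg4510.

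A fit of only the ages compared gave 0.109% for genotype at 3 months, 0.328% for genotype at 6 months, 0% for genotype by age 9 against 6, 13.5% for genotype by age 9 against 3, 7.75% for age 9 against 6 in non-transgenic and 0.109% for age 6 against 3 in rTg4510. EdgeR gave 6.55% for age 9 against 6 in non-transgenic. EdgeR with TMM factors gave 0.109% for genotype at 3 months, 0.109% for genotype at 6 months, 6.88% for genotype at 9 months, 0.218% for genotype by age 9 against 6, 1.86% for genotype by age 9 against 3, 0% for age 9 against 6 in non-transgenic and 3.93% for age 9 against 6 in rTg4510. DESeq2 gave 0.218% for genotype by age 9 against 6 and 15.9% for age 9 against 6 in non-transgenic. Leaving out Sample_207 and Sample_208 gave 0.218% for genotype at 6 months, 0.218% for genotype by age 9 against 6, 16.5% for age 9 against 6 in non-transgenic, 0.109% for age 6 against 3 in rTg4510 and 0.218% for age 9 against 6 in rTg4510. TMM rescaling without these libraries gave 0.109% for genotype at 3 months, 0.328% for genotype at 6 months, 19.4% for genotype at 9 months, 1.64% for genotype by age 9 against 6, 10.7% for genotype by age 9 against 3 and 5.79% for age 9 against 6 in rTg4510. Lanes 1 and 4 against 5 to 8 as a covariate gave 0.328% for genotype by age 9 against 6 and 0% for age 9 against 6 in non-transgenic. TMM rescaling with this covariate gave 0.109% for genotype at 3 months, 0.109% for genotype at 6 months, 16.7% for genotype at 9 months, 0.218% for genotype by age 9 against 6, 5.24% for genotype by age 9 against 3 and 0% for age 9 against 6 in non-transgenic. The characteristics as 1 covariate gave 27.2% for genotype at 9 months, 0% for genotype by age 9 against 6 and 6.33% for genotype by age 9 against 3. TMM rescaling with the characteristics as 1 covariate gave 0.109% for genotype at 3 months, 0.109% for genotype at 6 months, 7.10% for genotype at 9 months, 0% for genotype by age 9 against 6, 1.20% for genotype by age 9 against 3, 0% for age 9 against 6 in non-transgenic and 3.93% for age 9 against 6 in rTg4510. TMM rescaling in lane 8 alone gave 1.75% for genotype at 9 months. Lane 1 alone gave 0% for genotype at 9 months. TMM rescaling in lane 1 alone gave 0% for genotype at 9 months.

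Leaving out 1 library at a time gave 24.6% to 59.1% for genotype at 9 months, moved to 24.6% without Sample_203 and 26.0% without Sample_213. For genotype by age 9 against 6 the range was 0% to 20.3%, moved to 0% without Sample_181, Sample_183, Sample_186, Sample_191, Sample_197, Sample_198, Sample_202, Sample_203, Sample_204, Sample_208 or Sample_213, 0.218% without Sample_167, Sample_192, Sample_195 or Sample_214, 0.328% without Sample_166, Sample_173 or Sample_196, 0.437% without Sample_211, 0.764% without Sample_199, 0.983% without Sample_206, 12.8% without Sample_207 and 20.3% without Sample_205. For genotype by age 9 against 3 it was 2.29% to 46.5%, moved to 2.29% without Sample_213, 3.49% without Sample_180, 3.60% without Sample_203, 6.77% without Sample_166, 16.3% without Sample_176, 18.4% without Sample_214, 20.3% without Sample_199, 21.1% without Sample_208 and 21.4% without Sample_170. For age 9 against 6 in non-transgenic mice it was 0% to 20.3%, moved to 0% without Sample_183, Sample_195, Sample_213 or Sample_214, 0.109% without Sample_181 or Sample_204, 0.873% without Sample_202, 4.48% without Sample_180, 5.02% without Sample_203, 5.46% without Sample_205, 11.1% without Sample_192, 15.1% without Sample_166, 15.9% without Sample_207 and 20.3% without Sample_206. For age 9 against 6 in rTg4510 mice it was 0% to 0.218%, moved to 0.109% without Sample_203 or Sample_207 and 0.218% without Sample_199. The shares of genotype at 3 and 6 months, of their difference and of age 6 against 3 months in both genotypes stayed at 0.

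The typical level differed by 0.08 at 3 months (leaving out 1 library, -0.01 to 0.12), -0.02 at 6 months (-0.10 to 0.01) and -0.37 at 9 months (-0.45 to -0.31). Grouped by the characteristics it differed by 0.30 (exact permutation p = 0.0108), 0.16 (exact permutation p = 0.0325) and 0.27 (exact permutation p = 0.102), and in libraries whose labels give the same genotype by 0.37 at 3 months (exact permutation p = 0.1), 0.14 at 6 months (exact permutation p = 0.5) and -0.19 at 9 months (1 against 2 libraries, smallest possible p 0.333). At 9 months the characteristics disagree with the title for 8 of 11 libraries, so the 0.27 is not separate from the difference by title. By title at 9 months the typical level differed by -0.25 within lane 1 and -0.56 within lane 8. By the characteristics within single lanes it differed by 0.20 in lane 6 at 3 months, 0.25 in lane 7 at 6 months and 0.21 in lane 1 at 9 months (exact permutation p = 0.0833, 0.0952 and 0.314). The log2 ratio of B3 to B3A differed by 0.28 (0.27 to 0.29), 0.25 (0.24 to 0.26) and 0.19 (0.17 to 0.22) at the 3 ages. By the characteristics it turned to -0.020, -0.0085 and -0.083, and in libraries whose labels give the same genotype it was 0.26 at 3 and 0.24 at 6 months, where 3 against 3 libraries allow no p below 0.1. Within single lanes the ratio by the characteristics was -0.079 in lane 6 at 3 months, -0.18 in lane 7 at 6 months and -0.033 in lane 1 at 9 months. By title at 9 months the ratio differed by 0.14 within lane 1 and 0.27 within lane 8.

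Lists past the threshold numbered 0 and 0 for genotype at 3 and 6 months by camera on the deposited scale, and 1 and 1 after TMM rescaling. For genotype at 9 months they were 5, with 0 by an estimated correlation, 24 by fry, 2 after TMM rescaling and 0 with both. For genotype by age 9 against 6 they were 4, with 0, 0, 7 and 0 in the same order, and for 9 against 3 they were 5, with 0, 21, 3 and 0. For age 9 against 6 in non-transgenic mice they were 8, with 0 by an estimated correlation, 0 by fry and 1 by an estimated correlation after TMM rescaling. In rTg4510 mice they were 2, with 0, 0, 6 and 0, and for age 6 against 3 there 0, with 1 after TMM rescaling.

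For named elements, 85.6% of the values under the alternatives had the same direction and side of the threshold, 7.60% passed where the main value did not, 6.25% no longer passed and 14 values turned direction, all by grouping on the characteristics. At 9 months these were LTR81B (0.47), L1ME3G (0.58), IAPEY4_I-int (0.68), MamGypLTR3a (0.20), LTRIS4 (0.77), Tigger10 (0.70), MER77B (0.47), RLTR11C_MM (0.41) and Charlie4a (0.53). In the difference from 6 months it was IAPEY4_I-int (0.51), and in the difference from 3 months L1ME3G (0.28), IAPEY4_I-int (0.31), MER77B (0.080) and ORR1C1-int (0.21). All 14 values involve 9 months, where the characteristics disagree with the title for 8 of 11 libraries. That grouping is largely the reverse of the titles, so a turned direction there is not a separate test of these elements.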

Other observations

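The tests in this part were chosen after the data had been seen, apart from the grouping by the characteristics, which was planned.

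SINE and LTR shares differed slightly between genotypes at 3 months. Leaving aside ORR1A4 and L1Md_T, SINEs held 47.8% ± 0.31 (SD, n = 6) of the counts in rTg4510 and 47.0% ± 0.33 (n = 6) in non-transgenic libraries, with an exact permutation p of 0.00433 (adjusted over 15 comparisons, 0.0325). LTR elements held 24.4% ± 0.08 against 24.7% ± 0.09 (n = 6 each, exact permutation p = 0.00216, adjusted 0.0325). Without B3 the SINE shares were 45.0% and 44.8% (exact permutation p = 0.182) and the LTR shares gave an exact permutation p of 0.366.

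RLTR45-int, an internal part of an ERVK element, was higher in rTg4510 at 9 months after TMM rescaling in the fit without Sample_207 and Sample_208 (log2 fold change 1.41, adjusted p = 0.00135), as was UCON26 (1.36, adjusted p = 0.000499). With all libraries they were at 0.72 (adjusted p = 0.158) and 0.80 (adjusted p = 0.0902). Sample_207 and Sample_208 were left out after their values had been looked at, so the adjusted p without them do not test chance. On the log2 TMM scale RLTR45-int stood at 6.94 to 7.65 in the other 4 rTg4510 libraries and 5.77 to 6.30 in the other 5 non-transgenic libraries, with Sample_207 at 7.92 and Sample_208 at 5.56. MamGypLTR3a was lower in rTg4510 at 6 months in that fit, with a log2 fold change of -0.79 and an adjusted p of 0.000329. With all libraries the same fold change had an adjusted p of 0.400, and the SE was 0.23 against 0.13.

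The genotype in the characteristics went with the typical level of an element at 3 and 6 months. Libraries given as rTg4510 there lay 0.30 higher at 3 months (exact permutation p = 0.0108) and 0.16 higher at 6 months (exact permutation p = 0.0325). At 9 months they lay 0.27 higher (exact permutation p = 0.102), but the characteristics disagree with the title for 8 of 11 libraries of that age. The 0.27 cannot be told apart from the title difference of -0.37 with its sign turned. At 3 and 6 months the characteristics run in blocks of consecutive sample numbers and partly follow the lane, which these p-values ignore. Libraries given as rTg4510 there include all 3 outside lane 6 at 3 months and all 4 of lane 8 at 6 months. The difference was 0.20 within lane 6 at 3 months (exact permutation p = 0.0833) and 0.25 within lane 7 at 6 months (exact permutation p = 0.0952). The characteristics may carry a property of the libraries other than the genotype in the title. The ratio of B3 to B3A, which was picked after its values were seen, separated the titles of the 33 libraries other than Sample_207 and Sample_208 and did not differ detectably by the characteristics.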
